A study of Mus musculus with 16 samples.

How the data were processed

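RNA was measured in cells sorted by fluorescence from the olfactory mucosa of S100a5-tauGFP mice, a reporter line on C57BL/6 in which GFP marks olfactory sensory neurons through S100a5, a calcium-binding protein gene whose expression in these neurons rises with odor stimulation. Per the labels' protocols, 24 mice of both sexes, aged 7 to 12 weeks, spent 40 hours in clean-air chambers at an air flow of 3.1 L per minute. After the first 26 hours they received pulses of 10 seconds every 20 minutes, either of filtered air (vehicle) or of isoamyl acetate, an ester that smells of banana. The mice were sorted in pools of 3, and each of the 8 pools gave a library titled GFP+ and a library titled GFP-. That makes 16 arrays in 4 groups of 4: vehicle titled GFP+, vehicle titled GFP-, odor titled GFP+ and odor titled GFP-. Replicates within a group are therefore separate pools of 3 mice. The sex of each pool is not given in the sources used here.

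Biotinylated cRNA was made from 50 to 100 ng of total RNA and hybridised to Clariom S mouse arrays, per the labels' protocols. The authors deposited log2 signals, 1 value per probe set and array, made with Affymetrix Expression Console per the submitters' processing notes, which carry no version. The background correction and normalization used within that program are not given in the sources used here. The deposited log2 values run from 1.68 to 19.33 over 28846 probe sets. Of these, 6640 are controls, 5222 of them negative controls, and were left out of all tests, which leaves 22206. The array medians averaged 6.48 in libraries titled GFP- and 6.85 in libraries titled GFP+, so the deposited values were not brought to a common median. No pair of arrays held identical values.

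The platform annotation gave 1 gene symbol for 19572 of the tested probe sets, several for 0 and none for 2634. All 19572 Entrez identifiers were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. This table was used for names and for the order of neighbouring genes only. The named probe sets cover 19505 genes, of which 55 have several probe sets, and such a gene is represented by the probe set with the highest mean. None of the genes named in the text is among them. The array build is not given in the sources used here, so no coordinates are printed.

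Groups were taken from the sample titles. In all 16 samples the cell type field of the labels gives the opposite GFP sign to the title. Libraries are therefore called titled GFP+ and titled GFP- throughout, and every sort difference is titled GFP+ minus titled GFP-.

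The model was limma (version 3.58.1 in R 4.3.3), with lmFit on the 4 group means of all 16 arrays and eBayes without trend. It had 12 residual degrees of freedom and a prior of 4.49. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the 22206 tested probe sets of a comparison. The threshold was an adjusted p of 0.05. Unadjusted counts are of p below 0.05, which chance alone gives in a share of 0.05 of the tests. The 5 comparisons are the sort difference in vehicle, the sort difference in odor, the interaction of odor and sort (the sort difference in odor minus that in vehicle), and odor against vehicle within each titled sort. For the 1080 measured odorant receptor genes, calls were also counted with p adjusted over the list alone. The same was done for every other list, and where only 1 count is given the list alone gave the same.

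Of 30 gene lists written before the data were examined, 29 had at least 3 measured members: activity-dependent genes of olfactory neurons, immediate-early genes, axon guidance and adhesion genes, mature and immature olfactory neuron markers, neuronal progenitor and cell cycle genes, markers of horizontal basal, sustentacular, Bowman's gland, ensheathing glia, microvillar, respiratory, macrophage and neutrophil, lymphocyte, erythroid, endothelial and fibroblast cells, unfolded protein, heat shock, oxidative phosphorylation, synaptic vesicle and interferon genes, zone markers, necklace neuron genes, sex-linked genes, ribosomal proteins, and odorant, trace amine-associated and vomeronasal receptors. A list of class I receptors, written with newer symbols than the annotation uses, matched 0 genes and could not be tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. A list p-value given without further words is from the preset correlation. Lists share members with each other and with cell types beyond their names.

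Genes named in the text follow a rule also written before the data were examined: S100a5, up to 4 called members of each list with the largest differences (up to 2 as values where none was called), the 10 largest called rises and falls among genes whose replicates do not overlap, leaving out unnamed and provisional genes, and up to 20 receptors called over the list alone in the interaction and in odor against vehicle in titled GFP+. The text may use fewer. Exceptions are said in place.

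Each pool gave both sorts, so sort differences are paired by pool by design. The deviations from the group means of the 2 libraries of a pool correlated at 0.158 to 0.399, above 0.1 in 8 of 8 pools. A replicate block by pool was fitted as a fixed term for the sort differences and the interaction, and as a random effect (duplicateCorrelation of limma with statmod 1.5.0, consensus 0.234) for odor against vehicle. The replicate numbers shared between odor and vehicle are treated as numbers only.

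The other alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 33.3% of probe sets by mean signal (14804 kept), eBayes with trend and robust estimation, a threshold of 0.1, a fit on the groups compared alone, leaving out each array in turn, and the groups by the cell type field. Centring on mature olfactory neuron markers, and a term for the pair of replicate numbers (1 and 2, or 3 and 4) with fits within each pair, were chosen after seeing the data. Every sample column was used.

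Precision is limited by the 4 arrays per group, and depth has no count equivalent on arrays. The median of the negative controls lay between 5.15 and 5.67 on each array, and 56.9% to 64.2% of the tested probe sets were above it. Detection calls are not given in the sources used here, so the median negative control of each array, a choice made after seeing the data, served as the floor where a named gene was not above it in any library of a group. The fit was tested on simulated data drawn with the spread of the 22206 probe sets, with 50 changed at each of 4 sizes. For odor against vehicle in titled GFP-, it called 14% of log2 changes of 0.5, 62% of 1, 98% of 2 and 100% of 3, with 7 false calls. For the interaction it called 4%, 38%, 92% and 94% at the same sizes, with 5 false calls. With the pool block, the interaction was called for 0%, 26%, 90% and 94%, with 4 false calls. The simulated arrays were drawn independently, without a pool effect or a difference between replicate numbers. The rates may therefore not hold for the real arrays, where the libraries of a pool deviate alike. Figures were drawn with matplotlib 3.10.9.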

Results

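The series measured RNA in olfactory mucosa cells of S100a5-tauGFP mice after repeated pulses of filtered air or of isoamyl acetate. The assay asks which odorant receptors are expressed by neurons that respond to the odor: each olfactory sensory neuron expresses a single receptor gene, so receptors of responding neurons should be found more often among cells sorted for high GFP. The data are 16 arrays in 4 groups of 4, with 8 pools of 3 mice giving a library titled GFP+ and a library titled GFP- each. The titled sort parted the libraries on the first principal component, which held 74.0% of the variance. All values are log2 signals, and a difference of 1 is a change by a factor of 2.

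S100a5, the gene whose activity drives the reporter, was higher in the libraries titled GFP- in 8 of 8 pools. It averaged 16.39 ± 0.20 (SD, n = 4) in vehicle titled GFP- and 15.21 ± 0.47 in vehicle titled GFP+, a difference of -1.18 (SE 0.21, adjusted p = 0.000442). With odor it averaged 16.75 ± 0.18 in titled GFP- and 15.49 ± 0.31 in titled GFP+, a difference of -1.25 (SE 0.21, adjusted p = 0.000222). The pool differences ran from -0.86 to -1.45. The order goes against the titles and matches the cell type field of the labels, which gives each library the other sign. Every direction between sorts below is that of the titles and would turn if the cell type field holds. S100a5 was not called between odor and vehicle: the difference was 0.28 in titled GFP+ (adjusted p = 0.968) and 0.35 in titled GFP- (adjusted p = 1.00).

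**Figure D1:**
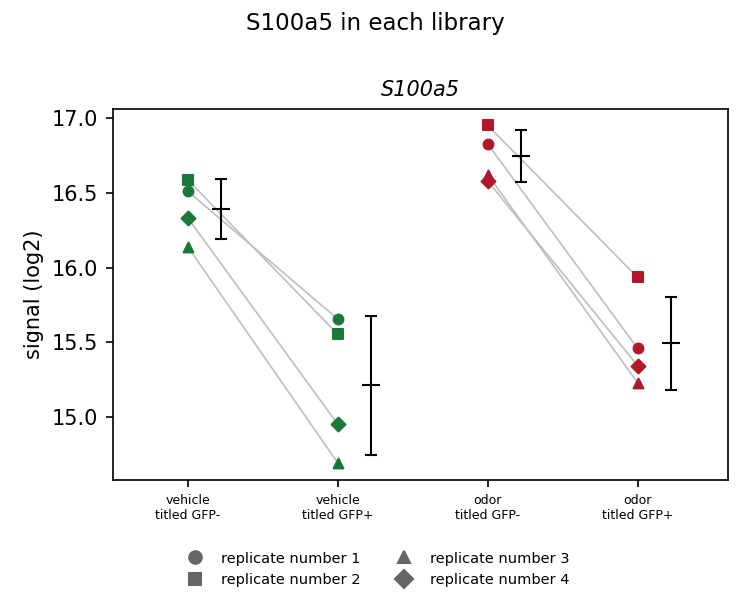
S100a5 signal (log2, vertical axis) in each of the 16 libraries by condition and titled sort, with lines joining the libraries of a pool and black bars for mean ± SD (n = 4). In all 8 pools the library titled GFP- lies above the library titled GFP+, by 0.86 to 1.45, going against the titles.

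In mice given filtered air, libraries titled GFP+ held much more RNA of immune cells than libraries titled GFP- of the same pools. Of 19 measured macrophage and neutrophil markers, 18 were higher and 0 lower, with a median difference of 5.24, and 18 were called adjusted over the list alone. The neutrophil granule gene Ngp was higher by 9.42 (SE 0.40, n = 4), S100a9 by 8.92 (SE 0.39) and S100a8 by 8.88 (SE 0.43). Lcn2 and Retnlg, also of neutrophils, were higher by 9.07 (SE 0.40) and 9.44 (SE 0.44), and the largest adjusted p of these 5 was 1.59e-10. Lymphocyte markers were higher in 9 of 10, 10 adjusted over the list alone, among them the antibody joining chain Jchain at 5.89 (SE 0.40) and Cd3e of the T cell receptor at 2.51 (SE 0.24). Of 3 erythroid markers 2 were higher, 3 adjusted over the list alone, including the anion exchanger Slc4a1 of red cells at 3.35 (SE 0.27). The list test gave adjusted p = 9.48e-51 for macrophages and neutrophils, 8.03e-09 for lymphocytes and 0.000504 for erythroid cells. With an estimated correlation these became adjusted p = 0.0164, 0.0454 and 0.0553.

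Markers of microvillar cells, and at the preset correlation of sustentacular cells, were also higher in vehicle libraries titled GFP+. All 13 microvillar cell markers were higher (13 adjusted over the list alone, median 2.50), with Foxi1 at 4.44 (SE 0.37), the taste-type channel Trpm5 at 3.57 (SE 0.48), Cftr at 3.28 (SE 0.47) and Alox5, which leukocytes express as well, at 5.03 (SE 0.43). Of 18 sustentacular markers 12 were higher, 14 adjusted over the list alone, with a median of 1.66, including Krt18 at 3.56 (SE 0.35) and the cytochromes Cyp1a2 at 2.80 (SE 0.41) and Cyp2a5 at 2.62 (SE 0.35). Among 13 Bowman's gland markers 3 were higher, both over all probe sets and over the list alone, led by Sox9 at 4.60 (SE 0.25) and by Ltf at 7.68 (SE 0.38), a protein of neutrophil granules too. The list's median was -0.06 while its test pointed up (adjusted p = 0.0116, and adjusted p = 0.214 with an estimated correlation). Microvillar and sustentacular markers gave adjusted p = 7.24e-15 and 1.61e-08 in the list test, and adjusted p = 0.0164 and 0.102 with an estimated correlation. Of 12 respiratory markers 3 were higher, led by Scgb1c1 at 4.04 (SE 0.37), and the list did not pass (adjusted p = 0.301). Of 9 horizontal basal cell markers 1 was higher, Cd44 at 5.14 (SE 0.41), which leukocytes also carry, and 2 adjusted over the list alone, and this list did not pass either (adjusted p = 0.271). Fibroblast markers were higher in 3 and lower in 1 of 11, with Fn1, also made by macrophages, at 8.56 (SE 0.47), without passing as a list (adjusted p = 0.110). Ensheathing glia markers were higher in 2 of 10 and endothelial markers in 1 of 10, and neither list passed its test.

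Libraries titled GFP+ in vehicle also held more RNA of immature neuron markers and of progenitor and cell cycle genes, beside the immune and epithelial markers above. Cell cycle genes mark dividing cells of any type. Immature neuron markers were higher in 12 of 19, with a median of 1.02, including Cd24a at 6.40 (SE 0.25), the bHLH factor Nhlh1 at 5.24 (SE 0.47) and the G protein subunit Gng8 at 4.69 (SE 0.32). Progenitor and cell cycle genes were higher in 11 of 13, 12 adjusted over the list alone, including Ube2c at 5.76 (SE 0.32), Mki67 at 5.44 (SE 0.38) and the stem cell factor receptor Kit at 3.17 (SE 0.25). Both lists kept their call, with adjusted p = 0.0240 and 0.0164 with an estimated correlation. Activity-dependent genes of olfactory neurons were lower in 5 of 9, 6 adjusted over the list alone and 8 with the pool as a replicate block. Besides S100a5 these included the calmodulin regulator relative Pcp4l1 at -1.62 (SE 0.30), the protocadherin Pcdh10 at -1.20 (SE 0.37) and Plcxd3 at -1.09 (SE 0.23). The list had a median of -1.09 and an adjusted p of 0.00357, which became adjusted p = 0.214 with an estimated correlation. Of 28 mature neuron markers 4 were lower and 0 higher, with a median of -0.12 (adjusted p = 0.0989). Median centring made 25 of 28 lower with a median of -0.50 (adjusted p = 0.0166, and adjusted p = 0.442 with an estimated correlation), and centring on these markers themselves, which holds them near 0, gave 0.06. The 4 include the transduction genes Pde1c at -0.66 (SE 0.12) and Ano2 at -0.45 (SE 0.12), and Ckb at -0.44 (SE 0.10). Axon guidance and adhesion genes were lower in 5 and higher in 1 of 23 (6 and 1 adjusted over the list alone), with the guidance receptor Epha5 at -1.04 (SE 0.19). Synaptic vesicle genes were lower in 2 of 20, Syn2 at -0.77 (SE 0.16) and Sv2b at -0.64 (SE 0.14). These counts depend on the scaling: under median centring 15 axon guidance and 16 synaptic genes were lower and 0 higher, and under centring on mature neuron markers 2 and 2 were lower and 2 and 1 higher.

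Immediate-early genes, transcribed within minutes of cell stimulation in many cell types, were higher in vehicle libraries titled GFP+ in 15 of 27 and lower in 0, with 16 higher and 1 lower adjusted over the list alone. Egr2 was higher by 6.02 (SE 0.40), Egr1 by 5.76 (SE 0.35), Btg2 by 5.32 (SE 0.37) and Fos by 5.06 (SE 0.43), in the same libraries in which neutrophil and progenitor markers were higher. The list's median was 1.60, with adjusted p = 1.72e-12 and adjusted p = 0.0460 with an estimated correlation, or adjusted p = 0.0631 with an estimated correlation after quantile normalization. Necklace neuron genes were higher in 6 of 10, 8 adjusted over the list alone, with the phosphodiesterase Pde2a at 3.34 (SE 0.23) and Ms4a6c, also a macrophage gene, at 4.43 (SE 0.35). That list gave adjusted p = 0.0164 with an estimated correlation. Interferon response genes were higher in 5 of 10, with Bst2 at 1.66 (SE 0.23), and the list gave adjusted p = 0.0188, or adjusted p = 0.102 with an estimated correlation. Ribosomal protein genes were higher in 28 of 59, including Rplp0 at 1.72 (SE 0.21) and Rps16 at 1.06 (SE 0.16), and 37 were higher and 2 lower adjusted over the list alone, but centring arrays on their medians left 11 higher and 3 lower. The list's adjusted p of 2.21e-07 became adjusted p = 0.214 with an estimated correlation. Heat shock genes were higher in 1 of 9, Hspb1, whose signal lay below the median negative control in all 8 vehicle libraries. With the pool block 4 were higher and the list passed (adjusted p = 0.0289, against 0.415 without the block and adjusted p = 0.628 with an estimated correlation), while interferon genes no longer did (adjusted p = 0.0535). Of the other stress lists, unfolded protein response genes were higher in 1 of 17 with 2 lower (2 and 2 adjusted over the list alone). None of the 19 oxidative phosphorylation genes, 8 zone markers or 3 sex-linked genes was called by limma. The median of the oxidative phosphorylation genes was -0.18, or -0.55 with 19 of 19 lower under median centring (adjusted p = 0.0384, and adjusted p = 0.330 with an estimated correlation), and turned to 0.01 with 0 called under centring on mature neuron markers.

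Odorant receptors parted strongly between the sorts in vehicle, in both directions. Of 1080 measured receptors 248 were higher and 442 lower in titled GFP+, and adjusted over the list alone 282 were higher and 486 lower. Olfr1507 was higher by 8.49 (SE 0.51), Olfr1213 by 8.38 (SE 0.79) and Olfr99 by 8.15 (SE 0.30). Olfr309 was lower, at -5.96 (SE 0.41), as were Olfr536 at -5.80 (SE 0.50), Olfr372 at -5.46 (SE 0.48), Olfr613 at -5.26 (SE 0.45), Olfr533 at -4.88 (SE 0.25) and Olfr110 at -4.86 (SE 0.33). The median receptor differed by -0.48, and stayed below 0 under each scaling tried, from -0.29 to -0.85. The list test did not pass as deposited (adjusted p = 0.395, and adjusted p = 0.674 with an estimated correlation), with the pool block (0.0549), after quantile normalization (0.243) or under median centring (0.202, pointing up), and passed under centring on mature neuron markers (adjusted p = 0.0276, pointing down). Trace amine-associated receptors were likewise split, with 5 of 14 higher, led by Taar2 at 4.23 (SE 0.45), and 8 lower, including Taar9 at -3.19 (SE 0.83) and Taar4 at -2.37 (SE 0.57). Vomeronasal receptors were lower in 35 of 319, and in 7 adjusted over the list alone, with a median of -0.27. Under median centring 230 were lower with a median of -0.64, and under centring on mature neuron markers 5 with a median of -0.08. Their list test gave adjusted p = 0.00236 (adjusted p = 0.0185 with an estimated correlation) and was lost after quantile normalization at the preset correlation (adjusted p = 0.120, but adjusted p = 0.0161 with an estimated correlation) and under median centring at the estimated one (0.0202 preset, adjusted p = 0.233 with an estimated correlation). The median negative control was also lower in vehicle libraries titled GFP+, at 5.17 to 5.43 against 5.40 to 5.67 in titled GFP-. This background difference was not taken out of the values for vomeronasal receptors.

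Over all probe sets, limma called 3851 in vehicle, 2260 higher and 1591 lower in titled GFP+, or 58.7% higher, and 4675 with the pool as a replicate block, 2421 higher and 2254 lower. The split depends on how arrays are scaled, since the median difference over all probe sets was -0.13 as deposited and -0.50 after centring on medians. Quantile normalization gave 2148 higher and 2954 lower (42.1% higher), median centring 1762 and 13868 (11.3%), and centring on mature neuron markers 2781 and 638 (81.3%). In the pools numbered 1 and 2 alone 2519 were called, and in those numbered 3 and 4 alone 2083. Some differences above are not exact, since the gene was not above the median negative control in any of the 4 libraries titled GFP-. With that median as the floor they are at least 7.24 for Fn1, 6.01 for Cd24a, 4.30 for Nhlh1, 4.23 for Jchain, 3.98 for Ube2c, 3.81 for Ms4a6c, 3.23 for Trpm5, 2.94 for Kit, 2.81 for Alox5 and 1.59 for Cd3e. Olfr613 was not above it in libraries titled GFP+, and its floored difference is -4.97.

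With isoamyl acetate, the sort difference had the same main parts. Macrophage and neutrophil markers were again higher in titled GFP+ in 18 of 19 (19 adjusted over the list alone, median 5.09), with Ngp at 8.76 (SE 0.40), S100a8 at 9.15 (SE 0.43), S100a9 at 8.98 (SE 0.39), Lcn2 at 9.59 (SE 0.40) and Retnlg at 9.41 (SE 0.44). All 13 microvillar markers were higher, with a median of 3.06, including Cftr at 3.83 (SE 0.47), Trpm5 at 3.67 (SE 0.48), Foxi1 at 4.00 (SE 0.37) and Alox5 at 5.24 (SE 0.43). Sustentacular markers were higher in 13 of 18, 14 adjusted over the list alone, with Krt18 at 4.12 (SE 0.35) and Cyp2a5 at 2.69 (SE 0.35). Lymphocyte markers were higher in 8 of 10, 9 adjusted over the list alone, with Jchain at 5.73 (SE 0.40), and erythroid markers in 2 of 3, with Slc4a1 at 2.64 (SE 0.27). As deposited, macrophage, microvillar and progenitor lists each gave adjusted p = 0.0178 with an estimated correlation, while sustentacular (adjusted p = 0.0927), lymphocyte (adjusted p = 0.0610) and erythroid (adjusted p = 0.0927) lists passed only at the preset one. Under median centring the lymphocyte list passed with an estimated correlation too (adjusted p = 0.0300), but the sustentacular and erythroid lists did not.

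Immature neuron markers were higher with odor in 10 of 19, 11 adjusted over the list alone, with Cd24a at 6.40 (SE 0.25) and Nhlh1 at 4.05 (SE 0.47), and progenitor genes in 11 of 13, 12 adjusted over the list alone, with Ube2c at 5.27 (SE 0.32). The immature list gave adjusted p = 1.41e-12, or adjusted p = 0.0610 with an estimated correlation, and adjusted p = 0.0451 with an estimated correlation after quantile normalization. Immediate-early genes were higher in 17 of 27, with 19 higher and 1 lower adjusted over the list alone. Egr2 stood at 6.77 (SE 0.40) and Egr1 at 6.23 (SE 0.35), and the list gave adjusted p = 0.0509 with an estimated correlation, or adjusted p = 0.0451 with an estimated correlation after quantile normalization. Activity-dependent genes were lower in 6 of 9, 7 adjusted over the list alone, with a median of -1.10, including Pcp4l1 at -1.90 (SE 0.30), Pcdh10 at -1.62 (SE 0.37) and Lrrc3b at -1.53 (SE 0.52), and the list gave adjusted p = 0.00319 (adjusted p = 0.185 with an estimated correlation). Mature neuron markers were lower in 4 of 28 with a median of -0.21, and in 25 with a median of -0.58 under median centring. Centring on these markers themselves holds them near 0, at 0.03. Their list test gave adjusted p = 0.0429 as deposited, or adjusted p = 0.366 with an estimated correlation, and adjusted p = 0.00657 under median centring (adjusted p = 0.401 with an estimated correlation). Axon guidance genes were lower in 6 and higher in 1 of 23 (7 and 1 adjusted over the list alone), with Epha5 at -1.09 (SE 0.19) and the semaphorin Sema7a at -0.83 (SE 0.14). Oxidative phosphorylation genes were lower in 4 of 19, 8 adjusted over the list alone, among them Ndufa2 at -0.52 (SE 0.15) and Uqcrc2 at -0.50 (SE 0.13), but in 19 of 19 under median centring (adjusted p = 0.00617, and adjusted p = 0.226 with an estimated correlation) and in 0 of 19 under centring on mature neuron markers. As deposited, that list's adjusted p of 0.0434 became adjusted p = 0.314 with an estimated correlation.

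Odorant receptors with odor were higher in titled GFP+ in 241 and lower in 466 of 1080, or 272 and 509 adjusted over the list alone, with a median of -0.57 that stayed below 0 under each scaling tried. The list test did not pass as deposited (adjusted p = 0.0851, and adjusted p = 0.534 with an estimated correlation), after quantile normalization (0.0650) or under median centring (0.677, pointing up). It passed, pointing down, with the pool block (adjusted p = 0.00584) and under centring on mature neuron markers (adjusted p = 0.000457). Olfr1507 stood at 8.42 (SE 0.51), Olfr99 at 8.37 (SE 0.30) and Olfr1213 at 8.29 (SE 0.79), and at the other end Olfr309 at -6.22 (SE 0.41), Olfr372 at -5.89 (SE 0.48) and Olfr536 at -5.82 (SE 0.50). Trace amine-associated receptors were higher in 5 and lower in 7 of 14, with Taar2 at 4.34 (SE 0.45), Taar4 at -3.50 (SE 0.57) and Taar9 at -3.31 (SE 0.83). Vomeronasal receptors were lower in 20 and higher in 1 of 319, with 1 lower adjusted over the list alone, with a median of -0.24. Under median centring 218 were lower with a median of -0.60, and under centring on mature neuron markers the median turned to 0.0017 with 2 lower. Their list test gave adjusted p = 0.0203, or adjusted p = 0.0610 with an estimated correlation, and at the preset one was lost after quantile normalization (0.147) and under median centring (0.0853). With an estimated correlation it gave adjusted p = 0.0368 after quantile normalization and adjusted p = 0.303 under median centring. The median negative control ran from 5.15 to 5.56 in odor libraries titled GFP+ and from 5.30 to 5.59 in titled GFP-.

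Among the remaining lists with odor, necklace genes were higher in 6 of 10 (adjusted p = 0.0178 with an estimated correlation), with Pde2a at 3.50 (SE 0.23) and Ms4a6c at 3.93 (SE 0.35). Ribosomal protein genes were higher in 30 of 59 (36 adjusted over the list alone), including Rplp0 at 1.57 (SE 0.21), but in 6 with 5 lower under median centring. Interferon genes were higher in 4 of 10 (4 higher and 1 lower adjusted over the list alone), with Bst2 at 1.84 (SE 0.23). Bowman's gland markers were higher in 3 of 13 (3 higher and 1 lower adjusted over the list alone), with Ltf at 8.55 (SE 0.38) and Sox9 at 4.52 (SE 0.25), and fibroblast markers in 3 of 11, with Fn1 at 8.35 (SE 0.47). As deposited, the ribosomal (adjusted p = 1.60e-06), interferon (adjusted p = 0.0434), Bowman's gland (adjusted p = 0.00311) and fibroblast (adjusted p = 0.0429) lists passed at the preset correlation only. They gave adjusted p = 0.219, 0.163, 0.0935 and 0.136 with an estimated correlation. Under median centring the Bowman's gland list alone of these passed with an estimated correlation (adjusted p = 0.0300). Respiratory markers were higher in 3 of 12 and lower in 1 (4 and 1 adjusted over the list alone), with Scgb1c1 at 4.29 (SE 0.37). Endothelial markers were higher in 3 of 10, horizontal basal cell markers in 2 of 9, including Cd44 at 3.71 (SE 0.41), ensheathing glia markers in 2 of 10 and heat shock genes in 1 of 9, Hspb1, which was above the median negative control in 1 of 8 odor libraries. With the pool block heat shock genes were higher in 4 of 9 (adjusted p = 0.0120, against 0.320 without it) and respiratory markers passed (adjusted p = 0.0402, against 0.105). Without the block these lists gave adjusted p = 0.513 and 0.300 with an estimated correlation. With it mature neuron and fibroblast (both 0.0551), oxidative phosphorylation (0.0806), interferon (0.0938) and vomeronasal lists (0.0510) no longer passed. Synaptic vesicle genes were lower in 5 of 20 (8 lower and 2 higher adjusted over the list alone), with Syn2 at -0.70 (SE 0.16) and Sv2b at -0.65 (SE 0.14). By limma 0 unfolded protein, zone or sex-linked genes were called as deposited, but under median centring 11 of 17 unfolded protein genes and 6 of 8 zone markers were lower, as were 14 of 20 synaptic vesicle and 18 of 23 axon guidance genes, and under centring on mature neuron markers 0, 0, 1 and 3.

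In the odor sort difference 4638 probe sets were called, 2449 higher and 2189 lower (52.8% higher). The pool block gave 5787, 2640 higher and 3147 lower, which turns the majority. Quantile normalization gave 2334 higher and 3300 lower (41.4%), median centring 1875 and 13679 (12.1%), and centring on mature neuron markers 3326 and 703 (82.6%). Within the pools numbered 1 and 2 the count was 3087, and within those numbered 3 and 4 it was 1990. Floored as in vehicle, the differences are at least 8.24 for Ltf, 6.84 for Fn1, 6.15 for Cd24a, 4.23 for Jchain, 3.75 for Ube2c, 3.50 for Ms4a6c and 3.26 for Alox5. The sort differences in vehicle and odor, which share no library, had 2974 calls in the same direction and 1 in the opposite one, where independent lists of these lengths would share 406. Across odorant receptors, which are not independent replicates, the differences correlated at r = 0.983, with 637 shared calls against 246 for independent lists.

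**Figure D2:**
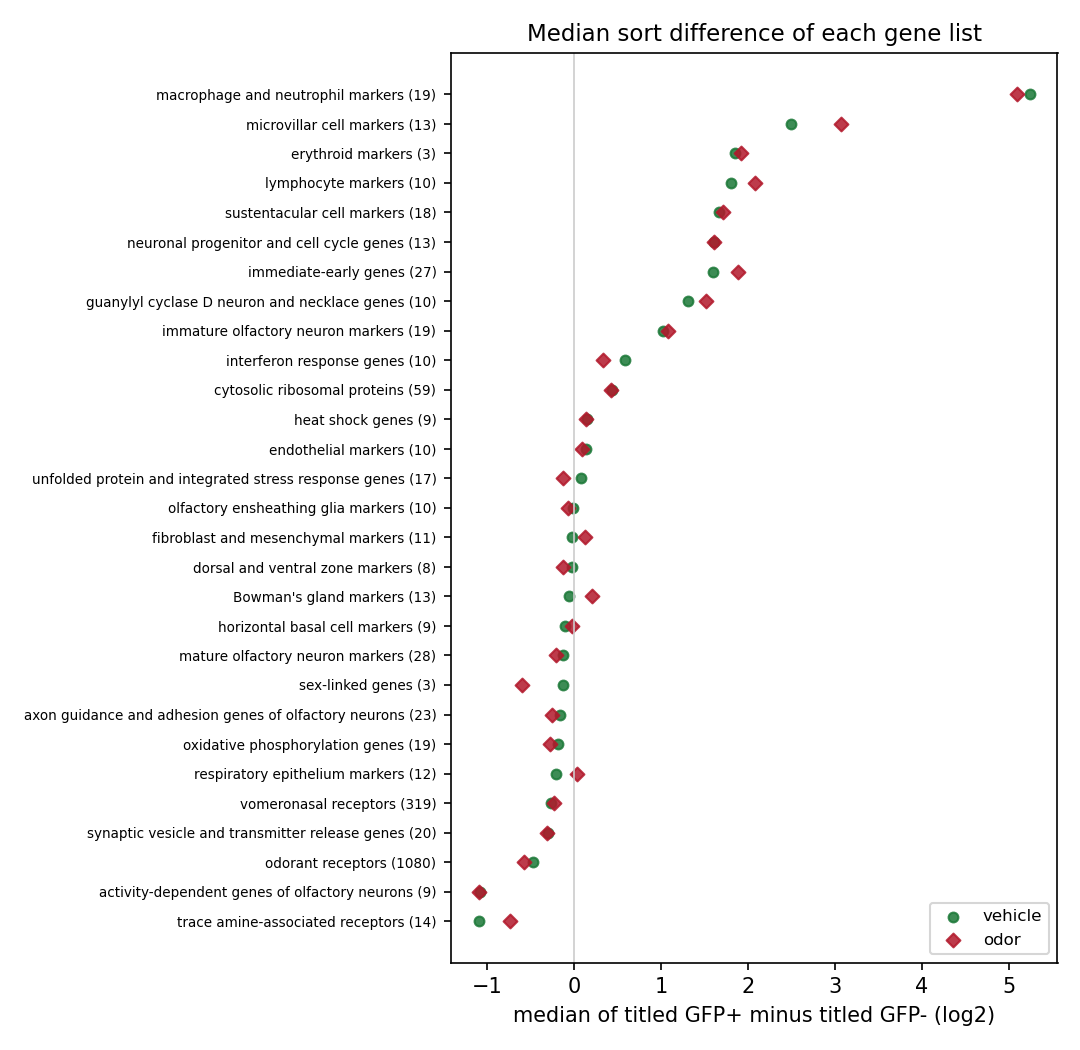
Median sort difference (titled GFP+ minus titled GFP-, log2, horizontal axis) of each gene list with at least 3 measured members, whose number stands in brackets, in vehicle (circles) and odor (diamonds). Macrophage and neutrophil markers lie highest at 5.24 and 5.09, and activity-dependent genes lie at -1.09 and -1.10. The signs follow the titles, which S100a5 goes against. With the scaling, medians of several lists near 0 move to either side of it, among them mature neuron markers in both conditions and vomeronasal receptors in odor (vomeronasal receptors in vehicle stay below 0).

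The interaction asks whether a gene is enriched in a sort more with isoamyl acetate than with air, which is where a receptor of responding neurons would stand out. Olfr170 alone was called over all probe sets. In vehicle it was at 10.16 ± 0.48 (SD, n = 4) in titled GFP- and 11.10 ± 0.44 in titled GFP+, and with odor at 12.27 ± 0.21 in titled GFP- and 9.91 ± 0.18 in titled GFP+. Its sort difference thus fell by 3.30 with odor (SE 0.33, adjusted p = 0.000416), toward the libraries titled GFP-, in which S100a5 is higher. Adjusted over the list alone, Olfr1411 was called as well: its sort difference fell by 1.75 (SE 0.33), from group means of 7.78 and 6.13 in vehicle to 8.50 and 5.09 with odor in titled GFP- and titled GFP+. Its adjusted p over the list alone was 0.0294, and 0.596 over all probe sets. Olfr1411 was above the median negative control in 1 of 4 odor libraries titled GFP+, and its interaction with that floor is -1.43. That makes 1 call over all probe sets, and 0 receptors higher and 2 lower over the list alone. An unadjusted p below 0.05 was reached by 653 probe sets, fewer than the share of 0.05 that chance alone gives.

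With the pool as a replicate block, 0 probe sets were called by limma over all 22206 (1092 at an unadjusted p below 0.05), and Olfr170 had an adjusted p of 0.0758. Over the receptor list alone the block gave 3 calls, Olfr170 (adjusted p = 0.00369), Olfr1411 (adjusted p = 0.00749) and Olfr213 (adjusted p = 0.0149), the last named after its value was seen. With the shared replicate number as block instead, which is no pairing by design, limma called the same 3 over all probe sets. Olfr213 had group means of 13.08 and 14.17 in vehicle and 14.97 and 13.46 with odor in titled GFP- and titled GFP+, and its difference fell by 2.61 (SE 0.53). Within the pools numbered 1 and 2 and within those numbered 3 and 4 the interaction was -4.15 and -2.45 for Olfr170, -2.27 and -1.24 for Olfr1411, and -2.74 and -2.48 for Olfr213. Olfr1411 lost its call when any 1 of 8 libraries was left out, with an adjusted p over the list alone of up to 0.0973 without the vehicle library titled GFP- of number 4. The interaction for S100a5 was -0.07 (SE 0.29, adjusted p = 1.00) and for Pcdh10 -0.42 (SE 0.53, adjusted p = 1.00). Immediate-early genes as a list passed at the preset correlation (adjusted p = 0.0194, median 0.24, 0 of 27 called by limma), and gave adjusted p = 0.952 with an estimated correlation.

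**Figure D3:**
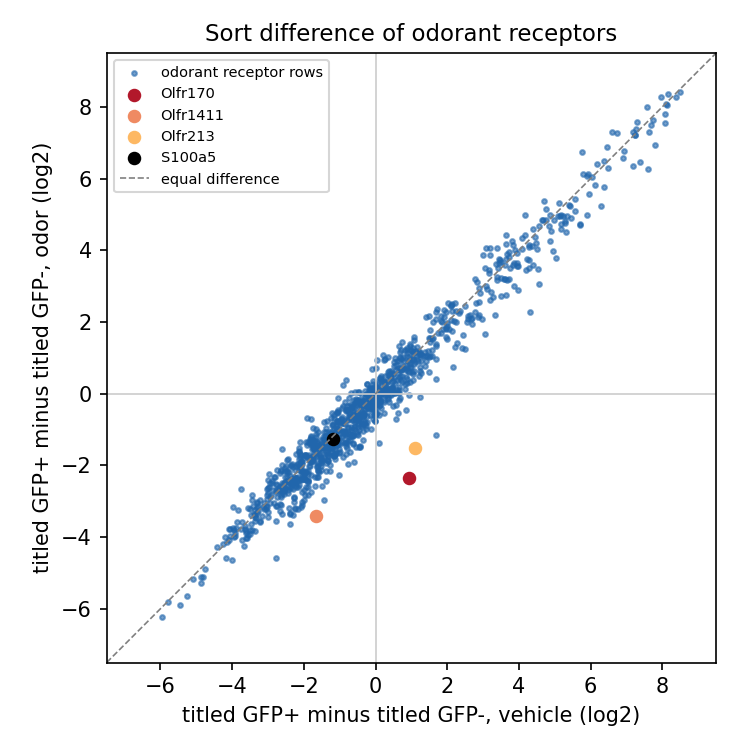
Sort difference (titled GFP+ minus titled GFP-, log2) of each odorant receptor in vehicle (horizontal axis) and odor (vertical axis), with S100a5 in black and a dashed line of equal difference. Receptors lie along the line with r = 0.983, while Olfr170, Olfr1411 and Olfr213 fall below it by 3.30, 1.75 and 2.61.

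**Figure D4:**
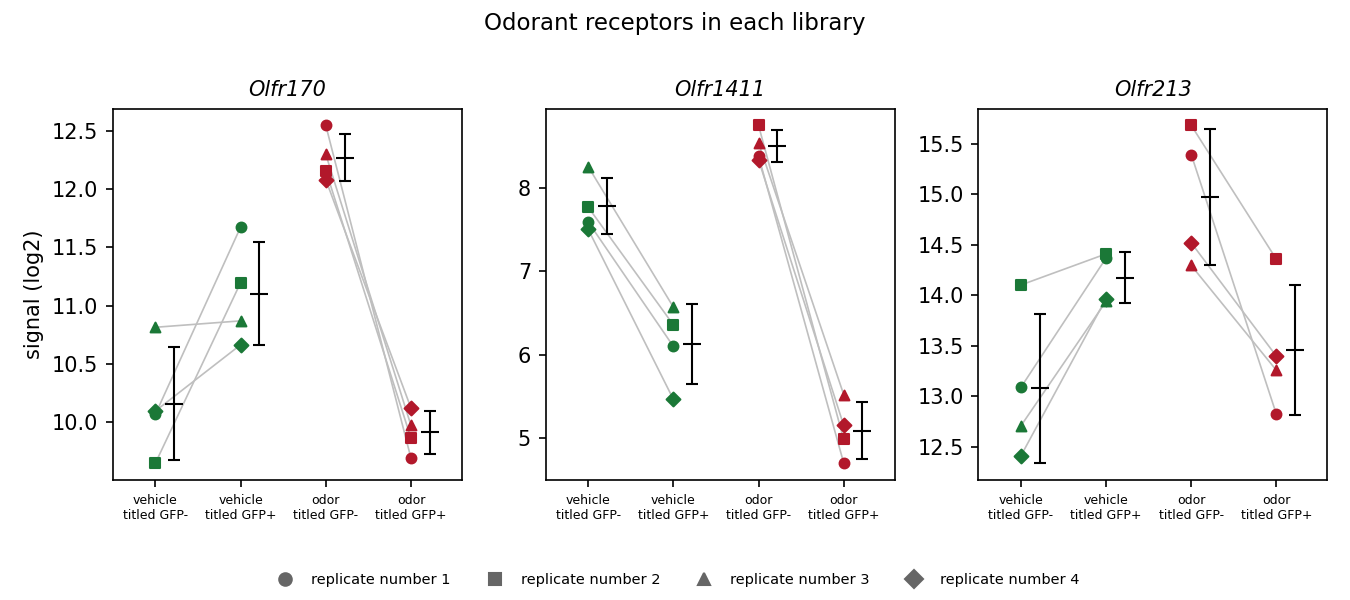
Signal (log2, vertical axis) of Olfr170, Olfr1411 and Olfr213 in each of the 16 libraries, with lines joining the libraries of a pool and black bars for mean ± SD (n = 4). With odor all 4 libraries titled GFP- lie above those titled GFP+ for Olfr170, whose means are 12.27 and 9.91, against 10.16 and 11.10 in vehicle.

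Within the libraries titled GFP-, 4 genes rose with isoamyl acetate and 0 fell. An unadjusted p below 0.05 was reached by 733 probe sets, fewer than chance alone gives. Pcdh10 rose from 9.07 ± 0.78 (SD, n = 4) to 12.06 ± 0.40, a change of 2.98 (SE 0.37, adjusted p = 0.00332). Camk2n1, an inhibitor of the kinase CaMKII, rose by 1.64 (SE 0.17, adjusted p = 0.000798), from 7.46 ± 0.18 to 9.11 ± 0.29. Olfr170 rose by 2.11 (SE 0.23, adjusted p = 0.000854), and Sema7a by 0.93 (SE 0.14, adjusted p = 0.0342), from 13.71 ± 0.19 to 14.64 ± 0.22. All 4 were also called with the pool block, but Sema7a was not under centring on mature neuron markers (adjusted p = 0.118) or on these groups alone (adjusted p = 0.601). Within the pools numbered 1 and 2, and 3 and 4, the changes were 2.83 and 3.13 for Pcdh10, 1.71 and 1.57 for Camk2n1, 2.49 and 1.73 for Olfr170, and 0.96 and 0.89 for Sema7a. Sema7a lost its call without any 1 of 6 libraries, with an adjusted p of 0.227 without the odor library titled GFP- of number 1. Olfr170 was the 1 receptor called over the list alone, and Olfr213 joined it with the pool block.

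Activity-dependent genes were the list with the smallest p in this comparison: 1 of 9, Pcdh10, was called, the median was 0.29, and adjusted p = 1.30e-05 became adjusted p = 0.936 with an estimated correlation. S100a5 was not called (0.35, SE 0.21). Sustentacular markers (median 0.23, adjusted p = 0.0177), oxidative phosphorylation genes (median 0.11, adjusted p = 0.0179) and trace amine-associated receptors (median -0.36, adjusted p = 0.0107) passed with 0 members called by limma, and each gave adjusted p = 0.936 with an estimated correlation. The median of all odorant receptors was -0.09, and that of macrophage and neutrophil markers 0.27. Cd44 stood at 1.86 (SE 0.41, adjusted p = 0.799) and was the 1 of 9 horizontal basal cell markers called adjusted over the list alone, and the heat shock gene Hspa1a, which spread widely between pools (SD 2.68 in vehicle), at -1.17 (SE 1.45, adjusted p = 1.00).

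**Figure D5:**
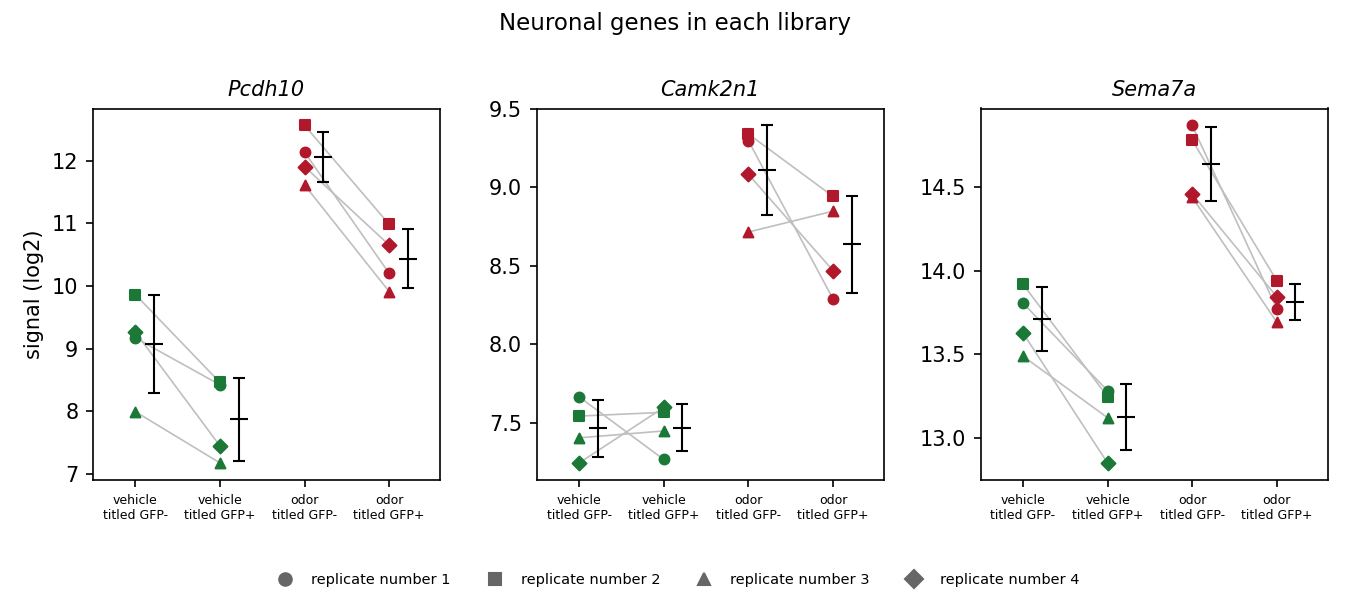
Signal (log2, vertical axis) of Pcdh10, Camk2n1 and Sema7a in each of the 16 libraries, with lines joining the libraries of a pool and black bars for mean ± SD (n = 4). Within each titled sort, every odor library of the 3 genes lies above every vehicle library. Over all probe sets Sema7a passed the test only in libraries titled GFP-, where its means are 13.71 and 14.64.

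Within the libraries titled GFP+, Pcdh10 and Camk2n1 rose with isoamyl acetate and 0 genes fell. An unadjusted p below 0.05 was reached by 1072 probe sets, no more than chance alone gives. Pcdh10 rose by 2.56 (SE 0.37, adjusted p = 0.0384), from 7.87 ± 0.66 (SD, n = 4) to 10.44 ± 0.48, and Camk2n1 by 1.17 (SE 0.17, adjusted p = 0.0384), from 7.47 ± 0.15 to 8.64 ± 0.31. Adjusted over the list alone 2 receptors fell, Olfr484 by 1.10 (SE 0.20) and Olfr170 by 1.19 (SE 0.23), both at an adjusted p of 0.0496, and 0 rose. With the pool block Pcdh10 alone was called over all probe sets (adjusted p = 0.0308). Camk2n1 then had an adjusted p of 0.0737, and over the receptor list alone 0 were called by limma, with Olfr484 at 0.0591 and Olfr170 at 0.0897 and 88 receptors at an unadjusted p below 0.05.

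The 2 calls in titled GFP+ became 0 under median centring (996 unadjusted), under eBayes with trend (1065) and on these groups alone (894), and the receptor calls became 0 after quantile normalization. Leaving out 1 library gave 0 calls without titled GFP+ libraries 2 or 4 of odor or any of the 4 of vehicle, and 6 without number 3 of odor. Within the pools numbered 1 and 2, and 3 and 4, Pcdh10 changed by 2.15 and 2.97 and Camk2n1 by 1.20 and 1.14. At the preset correlation immediate-early genes were higher as a list (median 0.62, adjusted p = 4.70e-09, 0 of 27 called by limma and 1 adjusted over the list alone), as were activity-dependent genes (median 0.28, adjusted p = 0.000342), sustentacular (median 0.37, adjusted p = 1.21e-05), Bowman's gland (adjusted p = 0.0374), microvillar (adjusted p = 0.0176) and respiratory markers (adjusted p = 0.0183). Immature neuron markers (median -0.28, adjusted p = 4.56e-05) and odorant receptors (median -0.19, adjusted p = 2.01e-06) were lower. None of these lists passed with an estimated correlation. Immediate-early, immature, Bowman's gland and respiratory lists gave adjusted p = 0.393, activity-dependent, sustentacular and receptor lists adjusted p = 0.431, and microvillar markers adjusted p = 0.561, each with an estimated correlation. The nuclear receptor Nr4a3, with the largest difference among the immediate-early genes, stood at 1.98 (SE 0.40, adjusted p = 0.416) and was called adjusted over the list alone. So were Sema7a (0.69) and Robo1 (-0.78) of the axon guidance list and Ms4a1 (-0.87) of the lymphocyte list, the last 2 named after their values were seen, and none of the 3 over all probe sets.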

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

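The tests chosen only after the result was seen are those on the order of S100a5 in the titles, on receptors related to Olfr170, on all receptors together, on other cell types, on cells of the other sort, and on which of the other splits keep the pools of a number together. The fits within a pair of numbers were added after the splits were seen, with the bounds set before these fits were run.

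Olfr170 and Olfr1411 stand out because their sort difference in odor was not that in vehicle, by a test of the difference itself: -3.304 for Olfr170 (SE 0.33, adjusted p = 0.000416 over all probe sets, but 0.0758 with the pool as a block and 0.00369 with the block over the receptor list alone) and -1.753 for Olfr1411 (SE 0.33, adjusted p = 0.0294 over the receptor list alone). Titled GFP- libraries held more Olfr170 than titled GFP+ libraries of the same pool in 4 of 4 odor pools and in 0 of 4 vehicle pools.

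A single library lay far from the other 3 of its group in 17 of 284 groups of 4 tested, where chance gives about 1 in 20, or 14.2. In odor titled GFP- number 3, Pcp4l1 was at 15.13 (others 15.78 to 15.84), Alox5 at 2.881 (3.63 to 3.71), Foxi1 at 6.832 (6.01 to 6.12) and Egr2 at 6.199 (6.94 to 7.07). In vehicle titled GFP+ number 3, Cyp1a2 was at 8.255 (9.31 to 9.46), Fos at 13.7 (15.18 to 15.45) and Btg2 at 10.6 (12.00 to 12.12). In vehicle titled GFP- number 3, Plcxd3 was at 8.18 (8.48 to 8.51) and Taar4 at 11.04 (9.03 to 9.36), and in odor titled GFP+ number 3 Fn1 was at 10.26 (12.82 to 13.08). Nhlh1 was at 10.26 in vehicle titled GFP+ number 2 (9.64 to 9.70), and Jchain at 3.606 in vehicle titled GFP- number 2 (3.92 to 3.93), Jchain and Alox5 being below the median negative control there. In odor titled GFP+ number 2, Lrrc3b was at 14.3 (12.40 to 12.68) and Ndufa2 at 11.08 (10.65 to 10.69). Sv2b was at 11.27 in odor titled GFP+ number 1 (11.65 to 11.67), Rplp0 at 9.821 in vehicle titled GFP- number 1 (10.27 to 10.32), and Hspa1a at 7.589 in vehicle titled GFP- number 4 (12.55 to 13.50). The total is near what chance gives, but 10 of the 17 lie in libraries numbered 3, where an even spread gives 4.25. Genes of 1 library do not vary independently, and no cause was tested.

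S100a5 was lower in the library titled GFP+ in 8 of 8 pools, while the mean of the macrophage and neutrophil markers was higher there, at 10.6 to 11.9 against 5.52 to 6.90. An exchange of single libraries would leave both orders among the pools, and 0 pools had S100a5 higher in the library titled GFP+. That the sort names are exchanged in the titles may explain the order in 8 of 8 pools, and the cell type field gives the names that way round. A sort in which the library titled GFP+ truly held the brighter cells would need S100a5 RNA to go against its own reporter. The mean of the activity-dependent genes, S100a5 among them, was also lower there in each pool, by -0.87 to -1.37. With the immune markers, this argues against such a sort. Immediate-early genes go the other way, with a median of 1.60 in vehicle. Many cell types transcribe them, and the same libraries held more immune RNA, so these genes do not decide the order. GFP itself was not measured here. The odor cannot account for the order, which vehicle pools share.

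For Olfr170 in the interaction, signal from receptors of the same family would move its relatives: the other measured members of family MOR273, Olfr1115, Olfr169 and Olfr171, stood at 0.02, -0.25 and -0.04, with a median of -0.041. A shift of all odorant receptors is excluded as the whole cause by their median of -0.10. Pools of one pair of replicate numbers alone would leave the other pair near 0, and the value nearer 0 was -2.45 (SE 0.35). This is no independent test, since Olfr170 was called in these same pools. Its sort difference is lower in each odor pool than in each vehicle pool, so a value of 0 or higher within a pair could not occur. Probe sequences are not given in the sources used here, so cross-hybridisation from unrelated genes stays open, as does chance. A response of neurons with Olfr170 to isoamyl acetate, which would move their RNA toward libraries with higher S100a5, may then be the reason for the value of -2.45 and its larger counterpart of -4.15, as a hypothesis found and tested on the same data.

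Camk2n1, Pcdh10 and Sema7a were higher with odor in titled GFP-. Admixture of another cell type would bring the type's other markers. The largest median change of a cell type list in titled GFP- was 0.27, for macrophage and neutrophil markers. That is below the smallest change of the 3 genes, 0.93. Those markers averaged 5.52 to 6.90 in titled GFP-, close to the negative control medians of 5.15 to 5.67. Sustentacular markers passed as a list at the preset correlation only (median 0.23, adjusted p = 0.0177). A list median near the floor cannot bound admixture, so admixture is not excluded. The lowest change within a pair of replicate numbers was 0.89, for Sema7a, so both pairs carry the rise. This is no independent test, since the 3 genes were called in these same libraries. Each of their odor libraries lies above each vehicle library, so a change of 0 or lower within a pair could not occur. In titled GFP+ the rise of Pcdh10 was 31.4% of that in titled GFP-, which cells of the other sort would have to supply. Olfr309 in titled GFP+ stood at 1.71% of its level in titled GFP-. That is the lowest share among 875 receptors above the median negative control in all 4 odor libraries titled GFP+. It leaves too little spill if spill takes all neurons alike. Neurons with other receptors that lie in both sorts are not bounded by this share and stay open as a source. The odor may raise Pcdh10 and Camk2n1 in cells of both sorts, with the sorts not shown to differ (interaction of Pcdh10 -0.42, adjusted p = 1.00), and in titled GFP- the 1 other split of 35 with as many calls is that of numbers 1 and 2 against 3 and 4, while in titled GFP+ 4 of 35 had as many.

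The 8 libraries of each sort difference, and the 8 pools of each other comparison, were also split in the 35 possible ways into 4 against 4. For the sort difference in vehicle 1 of 35 splits, the real one, gave as many calls as 3851 (highest other 0), and in odor 1 of 35 gave 4638 (highest other 2). These shares do not by themselves exclude chance, since the sorts are paired by pool. Of the 8 splits that part each pool, as the real one does, the other 7 gave 0 in either, and 1 of 8 is the smallest share these can give. A split that mixes the sorts also takes the sort difference into its spread, which lowers its count. For the interaction 4 of 35 splits gave as many as the real 1 (highest other 12), and for receptors in the interaction 2 of 35 gave as many as 2 (highest other 62). For odor against vehicle 2 of 35 gave as many as 4 in titled GFP- (highest other 89), 4 of 35 as many as 2 in titled GFP+ (highest other 309), and for receptors in titled GFP+ 9 of 35 as many as 2 (highest other 204). None of these 5 shares is under 0.05, so over all splits chance is not excluded. In each of the 5 the highest other split sets numbers 1 and 2 against 3 and 4, which points to a structure of the samples more than to chance. In titled GFP- and for receptors in the interaction it is the only other split as large, and in the interaction the other 2 also keep both pools of a number together. Of the 31 splits that part numbers, 0 were as large for these 3 counts, against 2 for titled GFP+ and 7 for its receptors. With a term for that pair of numbers, Olfr170 was again the 1 call in the interaction, Camk2n1 and Pcdh10 the 2 in titled GFP+, and Camk2n1, Olfr170, Olfr213, Pcdh10 and Sema7a the calls in titled GFP-.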

How the results depend on the processing

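Tests with centring on mature neuron markers, the term for the pair of numbers, and the fits within a pair were chosen after seeing the data. Replicate numbers that odor and vehicle share were also tried as a block. Libraries with the same number deviated alike, at correlations of 0.0729 to 0.406, above 0.1 in 7 of 8 cases and highest with their own number in 6 of 8.

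Of 2864 values of single genes under the alternatives, 2706 kept their direction and their side of the threshold, 142 lost the call, 11 gained one and 5 changed sign. All 5 are the interaction of S100a5, never called: 0.10 in numbers 3 and 4 alone, and up to 0.073 without vehicle GFP+ replicate 1, with -0.25 at the other end, without vehicle GFP+ replicate 3. Receptors in the interaction and in titled GFP+ were judged by the p over the list alone. Olfr170 in the interaction thus counts as kept with the pool block, though at 0.0758 over all probe sets. Most values are of sort differences. For odor against vehicle in titled GFP+, leaving out 1 library ended 25 of 48. None of the named genes has several probe sets. Taking groups from the cell type field turns the sign of each gene's sort difference and was not tabulated per gene.

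With the pool as a replicate block limma called 0 in the interaction (1092 unadjusted), 1 in titled GFP+ and 0 receptors there (88 unadjusted). Differences per pool gave 0 in the interaction as well (1092). With the shared number as block these were 3 (Olfr170, Olfr1411 and Olfr213), 1 (Pcdh10) and 4. The cause was not tested.

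Centring on array medians called 15630 in vehicle and 15554 in odor, which follows from the shift of the median difference to -0.50. It left 1 receptor in the interaction and 0 calls in titled GFP+ (996 unadjusted). Of the calls as reported, 3353 of 3851 in vehicle and 4064 of 4638 in odor were shared with it, 3509 and 4180 with quantile normalization, and 3681 and 4496 with the pool block.

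In titled GFP+, 0 receptors were called after quantile normalization (83 unadjusted), without the dimmest probe sets (77) and with centring on mature neuron markers (82), and 1 with the term for the pair of numbers. Trend and robust estimation left 0 calls there (1065 unadjusted). A threshold of 0.1 gave 5 receptors in the interaction and 4 in titled GFP+, as a looser threshold must. On the groups compared alone, titled GFP+ had 0 calls (894 unadjusted) and 0 receptors (115), and Sema7a in titled GFP- an adjusted p of 0.601. The cause was not tested.

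Numbers 1 and 2 alone, with fewer arrays, gave 2519 calls in vehicle, 3087 in odor, 4 receptors in the interaction, and 0 in titled GFP+ (1367 unadjusted), among its receptors (143) and in titled GFP- (859). Numbers 3 and 4 alone gave 2083 in vehicle, 1990 in odor, 0 in the interaction (761) with 1 receptor, and 0 in titled GFP+ (1238), among its receptors (140) and in titled GFP- (1269).

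Groups by the cell type field turn the directions by construction: 3851 in vehicle become 1591 higher and 2260 lower, 4638 in odor 2189 and 2449, the 1 in the interaction and its 2 receptors higher. Odor against vehicle then has 4 calls in GFP+ and 2 in GFP-, with 1 receptor in GFP+.

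Leaving out 1 library gave 3201 to 3599 calls in vehicle, 3571 to 4624 in odor, 1 to 2 in the interaction (2 without vehicle GFP+ replicate 4), 3 to 5 in titled GFP- and 0 to 6 in titled GFP+. Titled GFP+ had 0 without odor GFP+ replicates 2 or 4 or any of the 4 vehicle GFP+ libraries, 1 without odor GFP+ replicate 1 and 6 without odor GFP+ replicate 3. Its receptors ran from 0 (without odor GFP+ replicates 1 or 3, or vehicle GFP+ replicates 1, 2 or 3) to 4 without vehicle GFP+ replicate 4 and 11 without odor GFP+ replicate 2. Receptors in the interaction ran from 1, without the 8 libraries that end the call of Olfr1411 (GFP- replicates 1 and 2 and GFP+ replicates 1 and 4 of odor, GFP- replicates 1 and 4 and GFP+ replicates 1 and 3 of vehicle), to 4 without odor GFP- replicates 3 or 4 or either vehicle replicate 2, and 5 without odor GFP+ replicate 2. Sema7a in titled GFP- lost its call without odor GFP- replicates 1, 2 or 4 or vehicle GFP- replicates 1, 3 or 4. Olfr170 in the interaction was called in all 16. Signal over background limits the dim genes: 56.9% to 64.2% of probe sets lay above the median negative control.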

Other observations

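The comparison of pools by number was chosen only after the result of the 35 splits was seen, as was the test on Y-linked genes; the tests on X-linked genes, receptor class and neighbouring receptors were not.

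In libraries titled GFP-, some odorant receptors were much higher in the pools numbered 1 and 2 than in those numbered 3 and 4. The 4 given first were chosen after their values were seen, for differing in titled GFP- and not in titled GFP+. Others were larger than the smallest of the 4, such as Olfr231 at 3.15, Olfr1428 at 2.68 and Olfr1247 at 2.45. In numbers 3 and 4 Olfr231 lay at 2.87 to 3.47 in titled GFP-, below the negative control medians. Olfr235 was higher by 4.01 (SE 0.34, adjusted p = 5.42e-06), at 10.7 to 12.2 in the 4 pools of numbers 1 and 2 and 6.86 to 8.05 in the other 4. Olfr1431 was higher by 3.78 (SE 0.46), Olfr155 by 2.94 (SE 0.28) and Olfr16 by 2.39 (SE 0.26), with adjusted p-values of 0.000465, 2.46e-05 and 0.000141. In libraries titled GFP+ the same 4 differed by 0.56, 0.61, -0.28 and -0.43, with none called. Though the genes were chosen for it, the difference between the sorts is given as a value: it was past the threshold for Olfr235 (-3.45, adjusted p = 0.00818), Olfr155 (-3.21, 0.00587) and Olfr16 (-2.83, 0.00683). For Olfr1431 (-3.17) it was so over the receptor list alone (0.00688). In titled GFP+ Mki67 and Bub1 of dividing cells were higher in numbers 1 and 2, by 1.00 and 1.37. In all, 89 probe sets were called in titled GFP- (56 higher, 33 lower) and 309 in titled GFP+ (160 higher, 149 lower). Adjusted over the list alone, receptors were 105 higher and 102 lower in titled GFP-, and 13 higher and 191 lower in titled GFP+, or 105 and 95, and 12 and 212, after quantile normalization. Cell type markers moved with the same numbers in titled GFP+. In titled GFP- no marker of a cell type list was called, and the macrophage and neutrophil median went the other way, at -0.48. The mean macrophage and neutrophil signal in titled GFP+ was 11.3 to 11.9 in numbers 1 and 2 and 10.6 to 11.1 in numbers 3 and 4, and its sort difference 5.11 to 5.77 against 4.14 to 4.40. In titled GFP+ the median marker was higher in numbers 1 and 2 by 0.65 for macrophages and neutrophils, 0.93 for lymphocytes, 0.75 for microvillar, 0.58 for sustentacular and 0.50 for progenitor cells. In the same order, 3 of 19, 3 of 10, 3 of 13, 0 of 18 and 2 of 13 markers were called higher there, and the lists were not tested. The fall of receptors in titled GFP+ thus goes with higher medians of these markers, few of them called.

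The replicate numbers may part pools of male and female mice. The Y-linked genes Eif2s3y, Kdm5d and Uty were all above the median negative control in 8 of 8 libraries numbered 1 or 2 and in 0 of 8 numbered 3 or 4, with Eif2s3y at 9.61 to 10.6 against 2.53 to 3.49, Kdm5d at 5.90 to 7.86 against 2.29 to 3.20, and Uty at 9.38 to 11.3 against 2.91 to 4.24. A first, stricter bound, the 95th percentile of the negative controls (9.39 to 10.1), was passed by all 3 genes in 0 libraries, and the bound was changed after this was seen. The X-linked genes that escape silencing, Eif2s3x, Kdm5c and Ddx3x, had the higher mean in numbers 3 and 4 in 3 of 3, at 15.78 against 15.34, 10.21 against 10.17 and 16.50 against 16.36. Of these, Eif2s3x was called in titled GFP+ alone (-0.53, adjusted p = 0.0362), and the ranges of Kdm5c and Ddx3x overlapped between the pairs (16.2 to 16.5 in numbers 1 and 2 against 16.3 to 16.6 for Ddx3x). Those of Eif2s3x did not, at 15.06 to 15.51 against 15.68 to 15.95, so of these 3 genes the support rests on Eif2s3x. Kdm6a, also X-linked but not among the 3 tested, was called lower in numbers 1 and 2 in both sorts. It stood at -0.71 in titled GFP- (adjusted p = 0.00625) and -0.83 in titled GFP+ (adjusted p = 0.00171). Because 0 of 4 numbers hold pools of both kinds, the sex of the pools rather than anything else the numbers share, such as a day of work, cannot be told apart as the source of the receptor differences.

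Class I receptors were asked to sort differently from class II, and did not in vehicle: their medians were -0.49 (120 receptors) and -0.48 (940), with a permutation p of 0.954, and 20 receptors of unknown class were left out. Of the 5 comparisons the interaction alone gave a difference, -0.24 against -0.08 (permutation p = 0.00143, 0.00715 after Benjamini-Hochberg), but a permutation p of 0.0901 against the 108 class II receptors of chromosome 7, where class I genes lie. These permutations take receptors as units, which are not independent and do not measure the spread between pools.

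Neighbouring receptor genes of different MOR families may sort somewhat alike. Over 423 such neighbours the mean gap between their sort differences in vehicle was 2.36, against 2.59 in shuffled order (1-sided permutation p = 0.00993), and in odor permutation p = 0.0122. The permutation takes receptors as units, so its p does not measure the spread between pools. Odor is no second independent result, since the receptor differences in vehicle and odor correlate at r = 0.983. Neighbours of the same family, 620 pairs, had a mean gap of 2.34.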
